A study of Mus musculus with 19 samples.

How the data were processed

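RNA was measured on 19 Affymetrix mouse whole-transcript arrays, 8 of 3T3-L1 cells, 7 of embryonic and 4 of adult interscapular brown fat. Per the labels' protocols, total RNA was extracted with Trizol and prepared with the GeneChip WT PLUS kit and a biotin label. The authors deposited 1 table of log2 values for all arrays, and the submitters' processing notes name RMA and Transcriptome Analysis Console, with no version. RMA corrects the background, brings the arrays it is run on to one distribution and summarises the probes of each transcript cluster on a log2 scale. The genome build and annotation are not given in the sources used here. The deposited log2 values ran from 0.88 to 13.2. The median over the table was 4.69 to 4.79 in the cell arrays, 3.49 to 3.57 in the embryonic arrays and 2.87 to 2.89 in the adult arrays. The 3 experiments therefore look normalized in separate runs, and every test was made on differences within an experiment. No level is set against a level of another experiment.

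The table has 41345 transcript clusters. The platform annotation gave 1 gene symbol for 23521 of them, several for 1814 and none for 16010. Clusters with 1 symbol were kept, and for the 1082 genes with more than 1 cluster the cluster with the highest mean over all 19 arrays was used, which left 22180 genes. No filter on dim genes was set. RMA values carry no test against background, so a fold change is given as at least N-fold where every array of the dimmer group lay under its own lower quartile (3.49 to 3.56 in cells, 2.56 to 2.59 in the embryo and 2.22 to 2.24 in the adult), a rule set after the values were seen. A transcript cluster measures the probes it holds, so a probe set outside a deleted exon reads RNA of a deleted gene too.

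Groups were taken from the sample titles. For 4 of the 8 cell arrays the title and the source label disagree on the day: the arrays titled day 2 replicate 1 carry the label for cells before hormonal stimulation, and those titled day 0 replicate 2 the label for cells 2 days after it. Both labels put the same wild-type and knockout arrays side by side, so the comparison of genotypes over all 8 arrays used these 4 pairs as a block and holds under either label. The arrays of each pair also share their replicate number. Day-specific comparisons used the title, and the result with the source label is given with each of them. A group by the source label holds 1 array of each title day. Few or no calls with it are therefore what mixed days would give if the titles are right. No array was moved to another group because of its values. Nothing in the labels says whether replicates came from separate cultures, animals or litters, so p-values measure the spread between these arrays, which may in part be technical. The number of arrays limits the precision.

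Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust fitting, two-sided), with the Benjamini-Hochberg adjustment over all 22180 genes and a threshold of 0.05. The day-specific cell comparisons shared a fit of 4 groups over 8 arrays. The embryonic and adult brown fat arrays had a fit each, with 5 and 2 residual degrees of freedom, and the difference between their knockout effects came from a fit of all 11 brown fat arrays. Values after ± are standard errors of the log2 fold change unless SD is written. Gene lists, 30 in all, were fixed before the data were examined and tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera was also run with an estimated correlation, and fry was run as a test of whether a list's genes move one way on balance. A list needed 5 measured members. With an estimated correlation, only the hormone response list kept its camera call, in the comparisons of days. By fry, 35 of the camera calls of lists stayed and 48 did not.

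Genes were named by a rule fixed before the data were examined. The rule took 21 genes of adipocyte biology whatever their result, the 6 highest and 6 lowest fold changes among called genes whose arrays did not overlap between groups (4 and 4 for differences of differences), and up to 3 members of each list past its test. Predicted, unnamed, microRNA, small nucleolar RNA and olfactory receptor genes were left out of the ranked part. Genes outside this rule are said to be so where they appear.

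The fits were tested on simulated data with 200 changed genes among 22180. Noise was drawn independently for each gene, with its residual SD in these arrays taken as the true one. The shares and false calls therefore do not cover genes that vary together, as genes of these arrays may. The fits recovered 91% of genes changed 2-fold and 98% of those changed 4-fold for the genotype comparison over 8 cell arrays. The corresponding shares were 93% and 99% for embryonic brown fat, 0% and 40% for adult brown fat, and 29% and 84% for the genotype by day difference. For the other comparisons they were 60% and 96% (day 0), 67% and 97% (day 2), 68% and 96% (days in wild type), 66% and 95% (days in knockout) and 61% and 96% (adult against embryo). False calls were 14 of 170 on day 0 and 14 of 206 in the embryo. They were 10 of 167 for adult against embryo and 8 of 121 for the genotype by day difference. The remaining comparisons had 0 to 7 false calls.

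The alternatives tried were trend and robust fitting, leaving out the dimmer 50% of genes, repeated quantile normalization, median centring, the mean of all clusters of a gene, array weights, a fit of all 19 arrays, a block by replicate number, the source label for the day, a muscle covariate in the embryo, other thresholds, and leaving out each array in turn. All of these were chosen before the data were examined. Tables were prepared with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9.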

Results

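The series examined MED1, a subunit of the Mediator complex that links transcription factors to RNA polymerase II, in fat cells. One experiment used 3T3-L1, a mouse fibroblast line that turns into fat cells after a hormone cocktail, as the wild-type parent line and as MED1 knockout cells made with CRISPR/Cas9. The knockout arrays hold RNA pooled from individual clones. There were 2 arrays each of wild-type and knockout cells on day 0 and on day 2 of differentiation, by the sample titles. The other experiments used interscapular brown fat, the tissue that burns fat to make heat. Embryos at E17.5 carried Myf5-Cre with 1 floxed and 1 wild-type Med1 allele (3 control arrays) or with both alleles floxed (4 knockout arrays); Myf5-Cre acts in precursors of muscle and brown fat. Adult mice at 10 weeks had floxed Med1 without Cre (2 control arrays) or with Adipoq-Cre (2 knockout arrays), which acts in mature fat cells. Values are log2 RMA signals of 22180 genes.

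The first comparison asked which genes differ between MED1 knockout and wild-type 3T3-L1 cells whatever the day, over 4 pairs of arrays. Every pair set pooled clones against the parent line. Differences that arose in the cloning cannot be told apart from effects of MED1 loss, here and in the comparisons of genotypes by day. Med1 itself was 7.08 ± 0.07 (SD, n = 4) in knockout and 8.39 ± 0.16 (SD, n = 4) in wild-type cells, a 2.47-fold lower signal (adjusted p = 0.0011). Mest, an imprinted gene known from expanding fat tissue, fell 14.9-fold (log2 fold change -3.89 ± 0.17, adjusted p = 4e-04), and Sptlc3, a subunit of serine palmitoyltransferase, fell 5.72-fold (-2.52 ± 0.26). Tecrl, dim in wild-type cells (2.91 to 3.24), rose at least 6.39-fold (2.68 ± 0.14, adjusted p = 0.00071). Pdk4, a kinase that limits pyruvate use in mitochondria, fell 2.52-fold (-1.33 ± 0.08). In all, limma called 64 genes, 17 higher and 47 lower, each with the same sign in every pair.

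Among the other genes called lower, Ces2g (3.32-fold), Cygb (2.97-fold), Hmcn1 (2.94-fold) and Pi15 (2.87-fold) had the largest changes named by the rule. Brinp3 (3.6-fold), Serping1 (3.37-fold), Ptprn (3-fold), Cyth4 (2.32-fold) and Rspo3 (2.28-fold) rose. The regulators of fat cell formation did not pass over the pairs: Pparg had a log2 fold change of -1.4 ± 0.23 (adjusted p = 0.072), Cebpa of -0.9 ± 0.18 (adjusted p = 0.12) and the fat cell marker Fabp4 of -1.07 ± 0.37 (adjusted p = 0.31). Their wild-type SDs over both days were 1.17, 0.97 and 1.6. Cebpb, an early regulator, had a value of -0.08 ± 0.09.

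By groups, all 36 measured cell cycle genes had negative fold changes (median -0.34), with 1 called over all genes, Plk1 (-0.59 ± 0.08, adjusted p = 0.046), and 22 adjusted over the list alone. The list passed camera (adjusted p = 4.18e-20), and had an adjusted p = 0.386 with an estimated correlation. Of 26 interferon response genes, 25 were lower and Gbp3 was called (-1.14 ± 0.16), with 15 lower adjusted over the list alone. The list's median was -0.52 (camera adjusted p = 6.99e-13, and adjusted p = 0.781 with an estimated correlation). The mature adipocyte list (27 genes, median -0.13, 0 called, camera adjusted p = 0.0114), the brown fat list (30 genes, median -0.05, with Pdk4 called, adjusted p = 0.0411), the cholesterol synthesis list (18 genes, median -0.1, 0 called, adjusted p = 0.00942) and the nuclear respiratory chain list (38 genes, median -0.12, 0 called, adjusted p = 0.0011) were lower by camera. With an estimated correlation their adjusted p was 0.781, or 0.783 for cholesterol synthesis. Adjusted over the list alone, 1, 1, 1 and 0 of their genes passed. Leaving out any 1 of the 8 arrays with its pair left 20 to 32 genes called. Without the pair block 79 genes were called with days by the title, 38 of them among the 64, and 9 with days by the source label.

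On day 0, before the hormones by the title, 5 of 26 interferon response genes were called lower in knockout cells and 24 adjusted over the list alone (median -0.90, camera adjusted p = 4.35e-46, and adjusted p = 0.105 with an estimated correlation). Mx2 fell 4.02-fold (log2 fold change -2.01 ± 0.2, adjusted p = 0.011), Oas2 fell 3.85-fold (-1.95 ± 0.24) and Rtp4 fell 3.47-fold (-1.8 ± 0.17), all from 2 arrays against 2. Zbp1 and Ifih1 (outside the naming rule) were the other 2. The mean level of the list was 7.23 and 7.57 in the wild-type arrays and 6.33 and 6.37 in the knockout arrays.

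Among all 41 genes called on day 0 (6 higher, 35 lower), Mest (11.7-fold), the collagenase gene Mmp13 (7.18-fold), Sptlc3 (6.49-fold) and the relaxin receptor gene Rxfp1 (at least 4.11-fold) fell most. Tecrl (at least 5.35-fold), Serping1 (4.74-fold), Brinp3 (3.27-fold), Cyth4 (2.52-fold), Igfbp3 (2.38-fold) and Ankrd1 (2.2-fold) rose. Med1 had a log2 fold change of -1.24 ± 0.15 (adjusted p = 0.016). Pparg, at 5.06 ± 0.06 (SD, n = 2) against 5.85 ± 0.12 (SD, n = 2), had a log2 fold change of -0.79 ± 0.13 that missed the threshold (adjusted p = 0.065). The cell cycle (median -0.24, 0 of 36 called) and cholesterol synthesis (median -0.25, 0 of 18 called) lists passed camera, with adjusted p = 7.3e-06 and 0.00828. Neither had a gene past the threshold adjusted over the list alone, and both had an adjusted p = 0.928 with an estimated correlation. Without wild-type day 0 replicate 2 their medians were 0.02 and 0.19, and without knockout day 0 replicate 1 the cholesterol synthesis median was 0.1. With days by the source label, 1 gene (Mest) was called, the interferon median was -0.45 (camera adjusted p = 0.051), Mx2 had a value of -0.94, Oas2 of -0.51 and Rtp4 of -0.78. Leaving out 1 array left 3 to 40 genes called.

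On day 2 by the title, Pparg, Cebpa and 4 of 27 mature adipocyte genes were lower in knockout cells. Pparg, the nuclear receptor that drives fat cell formation, was 5.86 ± 0.02 (SD, n = 2) in knockout and 7.87 ± 0.1 (SD, n = 2) in wild-type cells, a 4.03-fold fall (adjusted p = 0.00037). Cebpa, its partner transcription factor, fell 2.57-fold (log2 fold change -1.36 ± 0.13, adjusted p = 0.0039), and Fabp4, a fatty acid binding protein of fat cells, fell 4.07-fold (-2.03 ± 0.24, adjusted p = 0.012). The lipid droplet gene Cidec fell 2.75-fold, Dgat2, which makes triglyceride, 2.07-fold, and Retn, the hormone resistin, 2.1-fold. Cebpb, which acts earlier, did not pass (-0.16 ± 0.15, adjusted p = 0.85). Of the 28 adipogenic regulators 3 were called lower, 4 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.129).

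In all, 59 genes were called on day 2, 7 higher and 52 lower. Pip (20-fold), Mest (18.9-fold), Sptlc3 (5.05-fold), the angiotensin receptor gene Agtr2 (4.72-fold) and the chemokine gene Cxcl13 (4.63-fold) fell most, with Fabp4. Tecrl (at least 7.64-fold), Brinp3 (3.97-fold), Lbp (3.24-fold), Emb (2.9-fold), Otulinl (2.62-fold) and Gstt1 (1.83-fold) rose. Med1 had a value of -1.38 ± 0.15 (adjusted p = 0.0078). Other genes of fat storage missed the threshold: Plin1 had a log2 fold change of -0.71 ± 0.2 (adjusted p = 0.35), Lpl of -0.86 ± 0.3, Srebf1 of -0.77 ± 0.25, Scd1 of -0.94 ± 0.42 and Adipoq of -0.43 ± 0.17. With days by the source label, which puts 1 array of each title day in a group, no gene was called (490 at an unadjusted p under 0.05, with 1109 expected by chance). Pparg then had a value of -1.29, Cebpa of -0.97, Fabp4 of -0.73, Cidec of -0.7, Dgat2 of -0.4 and Retn of -0.29.

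Of the 27 mature adipocyte genes, 4 were called lower on day 2 and 7 adjusted over the list alone (median -0.27, camera adjusted p = 2.43e-08, and adjusted p = 0.284 with an estimated correlation). Of 21 white fat genes, Mest and Retn were called lower, and 4 fell and 1 rose adjusted over the list alone (median -0.19, adjusted p = 0.00377, and 0.284 with an estimated correlation). None of 36 cell cycle genes was called over all genes and 14 were lower adjusted over the list alone (median -0.43, adjusted p = 2.21e-13, and 0.669 with an estimated correlation); Mcm6 had a value of -0.75 ± 0.13. Lists of brown fat genes (30 genes, Pdk4 called at -1.3 ± 0.17), the nuclear respiratory chain (38 genes, 0 called), the citric acid cycle (18 genes, 0 called) and epidermis (15 genes, Krt15 called at -1.35 ± 0.17) were also lower by camera. Of their genes 2, 0, 1 and 1 were lower adjusted over the list alone. Their medians were -0.11, -0.13, -0.15 and -0.14, and their adjusted p with an estimated correlation was 0.381, 0.82, 0.381 and 0.548. With the source label, the mature adipocyte median was -0.16 (camera adjusted p = 0.16), the white fat median -0.08 (adjusted p = 0.28) and the cell cycle median -0.37 (adjusted p = 2.1e-08). Leaving out 1 array left 12 to 47 genes called.

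**Figure D1:**
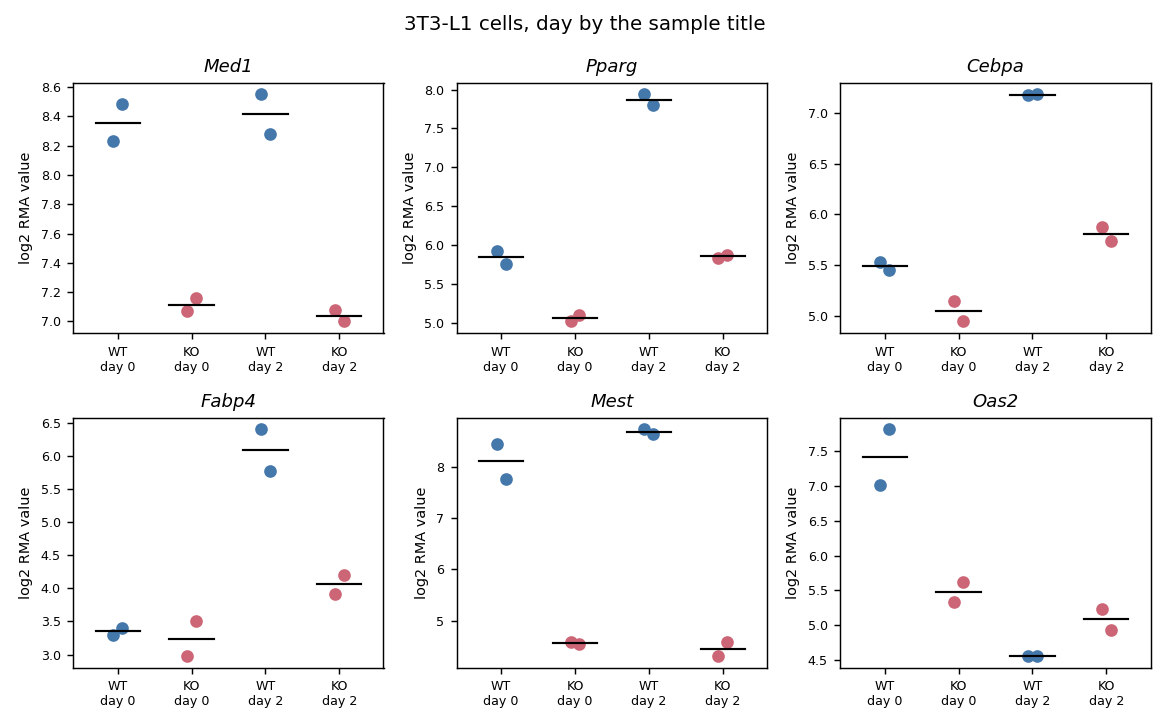
Log2 RMA values (vertical axes) of 6 genes in 3T3-L1 cells, with 1 point per array (n = 2 per group), lines at group means, wild type in blue and knockout in red, days by the sample title. The day 2 wild-type arrays lie above all others for Pparg (mean 7.87), Cebpa (7.18) and Fabp4 (6.09), and the day 0 wild-type arrays for Oas2 (7.42).

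From day 0 to day 2 by the title, limma called 2012 genes in wild-type cells, 762 higher and 1250 lower. Pparg rose 4.06-fold (log2 fold change 2.02 ± 0.13, adjusted p = 4e-05, n = 2 against 2), Cebpa 3.21-fold, Cebpb 3.57-fold and Fabp4 at least 6.66-fold (2.74 ± 0.24). Pip (at least 80.7-fold), Lcn2 (36.7-fold), the acute phase genes Orm3 (27.2-fold) and Orm2 (26.4-fold), Fam107a (19.2-fold) and Cxcl13 (14.4-fold) rose most. The glucocorticoid target Fkbp5 rose 7.99-fold and Glul, glutamine synthetase, 11.8-fold. Oasl2 (23.4-fold), Usp18 (20.4-fold), Ifit1 (19.6-fold), Apol9b (14.8-fold), Rtp4 (12.3-fold) and Mx2 (at least 17.3-fold) had the lowest fold changes named by the rule.

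Of 27 hormone response genes, 16 rose and 0 fell in wild-type cells, 19 adjusted over the list alone (median 1.40, camera adjusted p = 1.64e-15, and adjusted p = 0.0315 with an estimated correlation). Of 26 interferon genes, 21 fell, 23 adjusted over the list alone (median -2.29, adjusted p = 0.104 with an estimated correlation). Of 28 adipogenic regulators, 9 rose, Klf5 6.43-fold and Zbtb16 6.32-fold among them, and 2 fell. Of 27 mature adipocyte genes, 8 rose and 1 fell. Of 36 cell cycle genes, 10 rose, with Top2a up 5.83-fold and Pcna 3.05-fold. Of 17 hypoxia and glycolysis genes, 8 rose, such as Vegfa (3.29-fold). Of 28 fibroblast matrix genes, 12 fell and 1 rose, with Thbs2 down 4.95-fold and Pdgfrb 3.47-fold, and of 15 contractile genes 6 fell. Adjusted over the list alone, the counts of these 6 lists were 11 up and 4 down, 12 and 2, 15 and 0, 12 and 1, 2 and 12, and 0 and 7. Pcx rose 5.04-fold as the single citric acid cycle gene called (of 18), and Cycs rose 1.89-fold as the single respiratory chain gene called (of 38). No ribosomal protein gene of 24 was called (median 0.30). All of these lists passed camera, and apart from the hormone response list they had an adjusted p of 0.104 to 0.443 with an estimated correlation. With the source label no gene was called (650 at an unadjusted p under 0.05), and Pparg had a value of -0.16, Fabp4 of -0.27, Fkbp5 of -0.1 and the interferon median was 0.23. Leaving out 1 array left 1143 to 1714 genes called.

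In knockout cells by the title, 1265 genes were called between the days, 474 higher and 791 lower. Pparg rose 1.74-fold (log2 fold change 0.8 ± 0.13, adjusted p = 0.0063), Cebpa 1.69-fold and Cebpb 3.21-fold, and Fabp4 missed the threshold (0.82 ± 0.24, adjusted p = 0.088). Lcn2 (28.8-fold), Lbp (14.7-fold), Orm3 (14.2-fold), Fam107a (14-fold), Glul (11.7-fold) and Orm2 (10.7-fold) rose most. Oasl2 (10.1-fold), Akap12 (7.48-fold), the small heat shock protein gene Cryab (7.25-fold), Usp18 (7.16-fold), Cdsn (6.62-fold) and the complement gene C1s2 (at least 10.5-fold) had the lowest fold changes named by the rule. Of 27 hormone response genes, 16 rose, 18 adjusted over the list alone (median 1.36, adjusted p = 0.0146 with an estimated correlation), with Cebpd up 7.46-fold and Fkbp5 6.97-fold. Of 26 interferon genes, 15 fell, 20 adjusted over the list alone (median -1.07, adjusted p = 0.218 with an estimated correlation). Of 28 adipogenic regulators, 8 rose and 2 fell; of 17 hypoxia and glycolysis genes, 5 rose; of 28 fibroblast matrix genes, 7 fell, Dcn 5.01-fold among them; of 15 contractile genes, 5 fell. The counts adjusted over the list alone were, in this order, 9 up and 4 down, 9 and 1, 0 and 13, and 0 and 5.

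Of 36 cell cycle genes, Top2a (4.23-fold) and Pcna (1.87-fold) rose in knockout cells. Of 24 ribosomal protein genes, Rps7 rose (1.59-fold), and of 19 genes of the unfolded protein response, Herpud1 (2.24-fold) and Ddit3 (1.85-fold) fell. Another count, adjusted over the list alone, gave 2 cell cycle and 5 ribosomal protein genes up and 4 unfolded protein response genes down. These lists passed camera at the preset correlation, and apart from the hormone response list their adjusted p was 0.218 to 0.725 with an estimated correlation. With the source label no gene was called in knockout cells (559 at an unadjusted p under 0.05), and Pparg had a value of 0.06, Cebpa of -0.17 and the interferon median was 0. Leaving out 1 array left 496 to 1282 genes called.

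Whether the change over the days differed between genotypes was tested as a difference of differences. No single gene passed. The log2 difference, knockout minus wild type, was -1.22 ± 0.18 for Pparg, -1.91 ± 0.33 for Fabp4, -0.92 ± 0.18 for Cebpa and -1.47 ± 0.18 for Dgat2 (adjusted p = 0.18, 0.33, 0.52 and 0.11). It was 2.47 ± 0.34 for Oas2, 1.69 ± 0.24 for Rtp4 and 1.75 ± 0.29 for Mx2, with adjusted p of 0.16, 0.16 and 0.33. Mx2 was dim in both genotypes on day 2 (2.94 to 3.27), and Fabp4 was dim in both on day 0 (2.97 to 3.51). Of 26 interferon genes 0 passed over all genes and 16 were higher adjusted over the list alone (median 0.77), and of 27 mature adipocyte genes 0 and 6 lower (median -0.3); both lists passed camera, with an adjusted p = 0.151 with an estimated correlation. The cell cycle, citric acid cycle and white fat lists (medians -0.24, -0.16 and -0.1, with 0, 0 and 2 genes lower adjusted over the list alone) passed camera too, with an adjusted p of 0.84, 0.278 and 0.258 with an estimated correlation. Limma called 0 of 22180 genes, with 941 at an unadjusted p under 0.05 where chance gives 1109; the fit of all 19 arrays called 11. Differences for Cebpb (-0.15 ± 0.21), Fasn (-0.11 ± 0.28) and Acly (0.24 ± 0.3) were near their errors. With the source label Pparg had a difference of 0.21, Fabp4 of 0.69, Oas2 of -0.4, Rtp4 of -0.34 and Mx2 of -0.38, and the medians of the interferon and mature adipocyte lists were -0.28 and 0.02.

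In embryonic brown fat, 3 of 30 brown fat genes and 6 of 24 fatty acid oxidation genes fell and 1 of the latter rose in the Myf5-Cre knockout, while the skeletal muscle list, with no gene called, had a median of 0.82. These 3 lists passed camera, and each had an adjusted p = 0.269 with an estimated correlation. Ucp1, the protein that lets brown fat mitochondria make heat, was 7.63 ± 0.5 (SD, n = 4) in knockout and 10.76 ± 0.77 (SD, n = 3) in control arrays, an 8.79-fold fall (adjusted p = 0.044). Scd1, which desaturates fatty acids, fell 6.14-fold (log2 fold change -2.62 ± 0.41, adjusted p = 0.046), and Dio2, which activates thyroid hormone, fell 3.16-fold (-1.66 ± 0.17, adjusted p = 0.036). The brown fat noncoding RNA Lncbate10 fell 4.36-fold and Pank1, which starts coenzyme A synthesis, 3.39-fold. Of 36 cell cycle genes 12 rose, with Birc5 up 2.36-fold (1.24 ± 0.19) and Mcm6 up 2.04-fold, and the list had an adjusted p = 0.269 with an estimated correlation.

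Limma called 257 genes in the embryo, 146 higher and 111 lower. By sex-linked genes, control replicate 2 had the pattern of a female embryo and the other arrays that of males, so sex was not balanced between the genotypes. Gpd2 (3.71-fold) and Defb42 (3.53-fold) were among the lowest, and Egfl6 (2.9-fold), Tmem26 (2.74-fold), Phex (2.52-fold), Mmp2 (2.18-fold) and Bex3 (2.16-fold) among the highest. Fat cell regulators and markers did not pass: Pparg had a log2 fold change of -0.31 ± 0.08 (adjusted p = 0.11), Cebpa of -0.49 ± 0.12 (adjusted p = 0.079), Cidea of -1.21 ± 0.22 (adjusted p = 0.054), Ppargc1a of -0.49 ± 0.14 (adjusted p = 0.12), Fabp4 of -0.17 ± 0.06 and Prdm16 of -0.11 ± 0.19. Med1 was 6.94, 7.33 and 7.82 in the control arrays and 7, 7.1, 7.1 and 6.88 in the knockout arrays (-0.35 ± 0.19, adjusted p = 0.37). The probe set can lie outside the deleted part, the controls carry 1 floxed allele and the tissue holds other cells, so this value does not check the labels. Leaving out any 1 of the 7 arrays, controls and knockouts alike, left 0 genes called by limma, with 2991 to 4548 at an unadjusted p under 0.05 where chance gives 1109. Smallest adjusted p-values were then 0.051 to 0.11.

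By groups in the embryo, 6 of 24 fatty acid oxidation genes fell, Slc25a20 (2.7-fold), Ehhadh (2.07-fold) and Etfdh (1.77-fold) among them. Acot1, outside the naming rule, rose 1.54-fold. Of 18 citric acid cycle genes, 5 fell, such as Sucla2 (2.04-fold), Pdha1 (1.61-fold) and Idh3a (1.46-fold), and 18 adjusted over the list alone. Of 38 nuclear respiratory chain genes, Ndufs1 (1.51-fold) and Uqcrc2 (1.34-fold) fell, and 35 adjusted over the list alone. Of 30 brown fat genes, Ucp1, Dio2 and Slc25a20 fell, and of 13 thyroid hormone response genes, Ucp1, Dio2 and Thrb (2.24-fold), a thyroid hormone receptor. Of 27 lipogenesis genes, Scd1 fell, and Acly (-0.66 ± 0.12) and Acss2 (-1.26 ± 0.24) had adjusted p of 0.06 and 0.062. No mature adipocyte gene of 27 was called over all genes, and 20 were lower adjusted over the list alone, with Pck1 at -1.56 ± 0.3. Adjusted over the list alone, 20 fatty acid oxidation, 16 brown fat, 8 thyroid response and 16 lipogenesis genes were lower, and 1 fatty acid oxidation and 3 brown fat genes higher. These 7 lists passed camera, each with an adjusted p = 0.269 with an estimated correlation.

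Ube2c (1.52-fold) and Rrm2 (2.05-fold) were among the 12 cell cycle genes that rose in the embryonic knockout, and 35 of 36 were higher adjusted over the list alone. Of 28 fibroblast matrix genes, 5 rose, with Loxl1 up 1.56-fold and Col1a1 1.52-fold. Of 15 contractile genes, 3 rose: Cnn1 (1.71-fold), Acta2 (1.7-fold) and Tpm1 (1.49-fold). Cnn1 and Acta2 are also on the smooth muscle list of 13 genes (median 0.1). Of these lists 20 fibroblast matrix, 7 contractile and 4 smooth muscle genes were higher adjusted over the list alone. The skeletal muscle list was higher by camera at its preset correlation (median 0.82). No gene of 32 was called over all genes, and 22 were higher adjusted over the list alone. Actn2 had a value of 1.6 ± 0.4 (adjusted p = 0.091). The mean level of the list was 5.85, 5.86 and 5.02 in the control arrays and 6.46, 6.3, 6.3 and 6.3 in the knockout arrays. Ribosomal protein (median 0.26, 0 of 24 called, 10 adjusted over the list alone) and macrophage genes (median 0.17, 0 of 21) were higher, and hormone response (median -0.09, 0 of 27) and hypoxia genes (median -0.24, 0 of 17) lower by camera. The 9 lists of this paragraph passed camera, and none did with an estimated correlation (adjusted p = 0.269 to 0.502). With the mean of the muscle list as a covariate 0 genes were called by limma (1268 at an unadjusted p under 0.05), and Ucp1 had a log2 fold change of -1.99 ± 0.5. Median centring called 386 genes.

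In adult brown fat with Adipoq-Cre, the noncoding RNA Lncbate10 fell 17.3-fold (log2 fold change -4.11 ± 0.26, adjusted p = 0.049, n = 2 against 2), Mfsd4b1 fell 4.45-fold and Oxct1, which lets cells use ketone bodies, fell 4.04-fold (-2.01 ± 0.13). Ephx1, an epoxide hydrolase, rose 7.25-fold (2.86 ± 0.17) and Matn2, a matrix protein, rose 5.29-fold (2.4 ± 0.14). Limma called 6 genes, 3 higher and 3 lower, with 3013 at an unadjusted p under 0.05 where chance gives 1109. The sixth, Gm6644, is outside the naming rule and was named after its values were seen. Med1 was 5.99 and 6.9 in the control arrays and 5.28 and 5.13 in the knockout arrays (-1.24 ± 0.31, adjusted p = 0.19).

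Several metabolic genes had large changes in the adult that did not pass. Cpt1a, the liver form of the enzyme that brings fatty acids into mitochondria, had a log2 fold change of 3.42 ± 0.35 (adjusted p = 0.059). Elovl3, a brown fat elongase, had a value of -3.66 ± 0.58 (adjusted p = 0.1), Ppara of -3.46 ± 0.34 (adjusted p = 0.055), Pck1 of -3.24 ± 0.41, Ppargc1b of -3.01 ± 0.27 and Retn of -2.73 ± 0.26. Cebpa (-1.53 ± 0.25), Cidea (-1.37 ± 0.14), Scd1 (-1.09 ± 0.21), Ucp1 (-0.97 ± 0.32) and Pparg (-0.7 ± 0.14) were lower, with adjusted p of 0.11, 0.059, 0.13, 0.29 and 0.14. Adipoq had a value of 0.28 ± 0.13 (adjusted p = 0.45) and Fabp4 of -0.16 ± 0.17 (adjusted p = 0.78). Dio2 was 5.07 and 9.49 in controls and 4.99 and 7.5 in knockouts, so that replicates differed more than genotypes. Leaving out any 1 of the 4 arrays left 0 genes called by limma (1984 to 2333 at an unadjusted p under 0.05), while trend and robust fitting called 78 and the fit of all 19 arrays 2049.

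Macrophage genes were the group with the highest median in the adult knockout. All 21 had positive fold changes (median 1.28), 0 were called over all genes and 19 were higher adjusted over the list alone, with the complement gene C1qc at 1.61 ± 0.15, Cd14 at 1.44 ± 0.14 and H2-Aa at 1.38 ± 0.13, each with an adjusted p of 0.052. Of 28 fibroblast matrix genes, 16 were higher adjusted over the list alone (median 0.63), with Lum at 1.41 ± 0.17. Of 15 lymphocyte genes, 3 were (median 0.24), with Cd3e at 1.23 ± 0.21. Interferon (median 0.33), ribosomal protein (0.25), unfolded protein response (0.40) and cell cycle (0.12) lists were higher too, with 0, 0, 1 and 0 genes adjusted over the list alone. These 7 lists passed camera, and none did with an estimated correlation (adjusted p = 0.33 to 0.543).

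Lists of brown fat (median -0.54), mature adipocyte (-0.42), fatty acid oxidation (-0.41), citric acid cycle (-0.33), nuclear respiratory chain (-0.29), lipogenesis (-0.24) and thyroid hormone response genes (-0.49) were lower in the adult knockout. Adjusted over the list alone, 10, 11, 6, 7, 0, 6 and 0 of their genes were lower, and 3 brown fat genes, Cpt1a of the oxidation list and 1 gene each of the cycle and lipogenesis lists were higher. No member of these lists was called over all genes. These lists passed camera as well, and with an estimated correlation their adjusted p was 0.33 to 0.543.

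**Figure D2:**
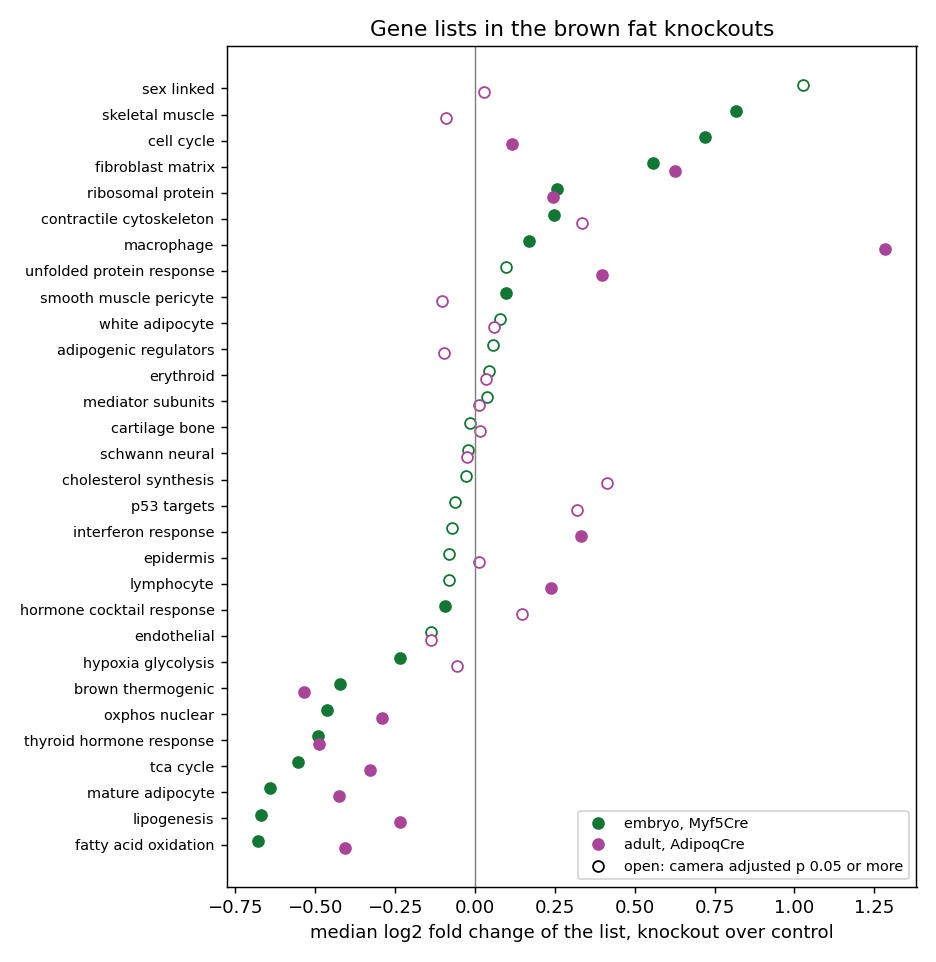
Median log2 fold change, knockout over control (horizontal axis), of each of the 30 gene lists in embryonic (green, n = 3 and 4) and adult (purple, n = 2 and 2) brown fat; filled points passed camera at its preset correlation. The macrophage list lies at 0.17 in the embryo and 1.28 in the adult, and the skeletal muscle list at 0.82 and -0.09.

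**Figure D3:**
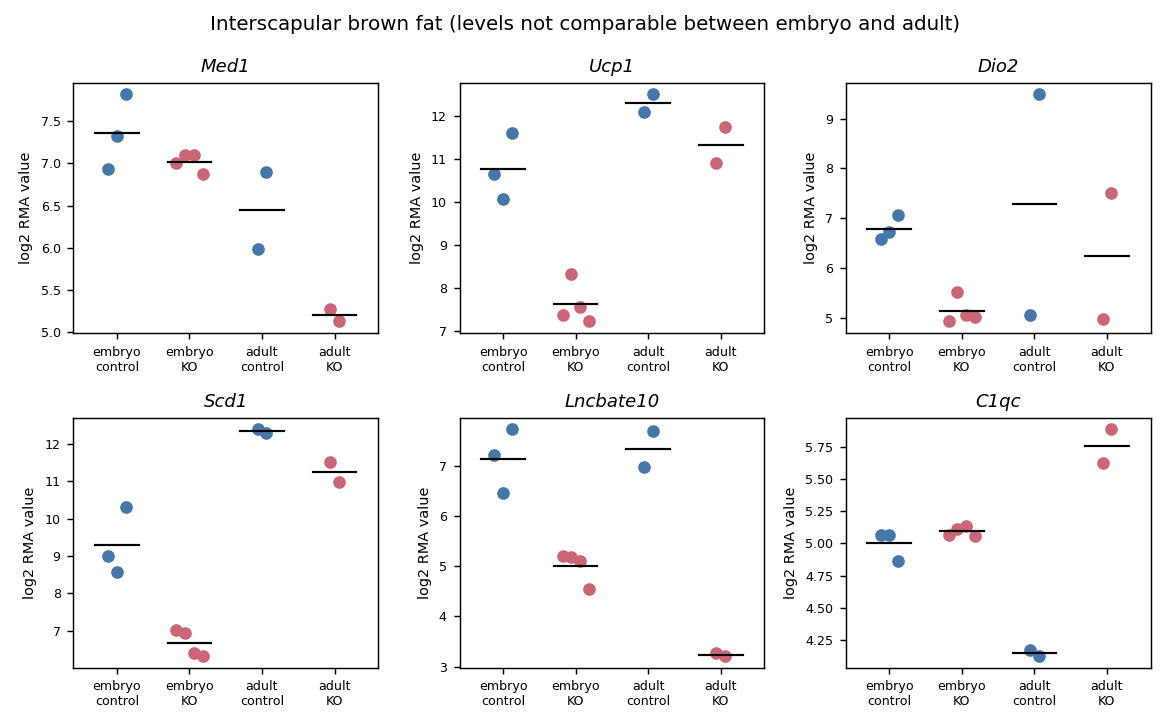
Log2 RMA values (vertical axes) of 6 genes in brown fat, with 1 point per array, lines at group means, controls in blue and knockouts in red; embryo and adult levels look normalized in separate runs and were not set against each other. The knockout arrays lie below the control arrays of the same age for Ucp1, Scd1 and Lncbate10, and the C1qc means are 5.76 in adult knockouts and 4.15 in adult controls.

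The knockout effects of adult and embryonic brown fat were compared as a difference of differences, since the 2 sets look normalized in separate runs. Age, Cre line and control genotype differ together between the sets. The fit used 1 estimate of the spread per gene for both sets. Where the adult arrays spread more than the embryonic ones, it understates the error of the adult part. The standard error of the difference was 1.41 for Dio2 and 0.14 for C1qc, against 1.58 and 0.15 for the adult effect alone. A gene can thus pass here without passing in the adult. Macrophage genes differed most as a group: 7 of 21 passed with a higher value in the adult effect, such as H2-Aa (log2 difference 1.63 ± 0.16, adjusted p = 0.0025), C1qc (1.52 ± 0.14, adjusted p = 0.0016) and Cd14 (1.47 ± 0.17), and 18 did adjusted over the list alone (median 1.01, adjusted p = 0.197 with an estimated correlation). Cd3e (1.41 ± 0.19), Cd4 (0.83 ± 0.16) and Nkg7 (0.69 ± 0.14) passed as 3 of 15 lymphocyte genes (4 adjusted over the list alone). The adult effect was higher for Cpt1a (9.29-fold), Ptges (8.84-fold), Nr4a2 (8.55-fold) and Aqp11 (7.34-fold). It was lower for Cyp2e1 (19.4-fold), Rhou (5.91-fold), Ppargc1b (5.11-fold) and Retn (5.11-fold).

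In all, 441 genes differed between the adult and embryonic effects, 285 higher and 156 lower. Ucp1 had a difference of 2.16 ± 0.6 (adjusted p = 0.11), Scd1 of 1.53 ± 0.58 and Elovl3 of -2.99 ± 0.74 (adjusted p = 0.072), while Cidea (-0.16 ± 0.31) and Fabp4 (0 ± 0.15) were within their errors. Ube2c (-0.79 ± 0.17) was the single cell cycle gene of 36 to pass, with 13 adjusted over the list alone (median -0.6). Psmb8 of the interferon list (0.62 ± 0.14), Ccng1 of the p53 list (0.82 ± 0.15) and Suclg2 of the citric acid cycle list (0.91 ± 0.17) passed too. Of 32 skeletal muscle genes 0 passed (median -0.92). In all, 12 lists passed camera, and none did with an estimated correlation (adjusted p = 0.197 to 0.818). Array weights called 128 genes and leaving out 1 array 206 to 524.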

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

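The fit with the muscle covariate, the counts of splits and the test of the day labels were chosen before the data were examined; the test of fat and mitochondrial lists in that fit and the tests of dilution, of the interferon list and of the macrophage list were chosen after their results were seen. The muscle covariate was first read on the 111 genes called lower in the embryo, whose median went from -0.79 to -0.54, and on these genes muscle as the whole cause had been excluded. That reading was replaced, as the genes were picked by the result under test, and the one on preset lists leaves this cause open.

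In Myf5-Cre knockout embryos fat and mitochondrial lists were lower and the muscle list higher by camera, each with an adjusted p = 0.269 with an estimated correlation, and few genes were called: 6 of 24 (fatty acid oxidation), 5 of 18 (citric acid cycle), 3 of 30 (brown fat), 2 of 38 (respiratory chain), 1 of 27 (lipogenesis) and none of the mature adipocyte and skeletal muscle lists. Of the 35 splits of the 7 arrays, 1, the real one, called as many as 257 genes, and the highest other called 0, so a random split is excluded at this level. More skeletal muscle in the knockout dissections might be the cause and is not excluded. With the muscle list mean as a covariate, the median of the 154 preset fat and mitochondrial genes went from -0.56 to -0.29. It kept 52.2% of its value, and the median SE of a member gene went from 0.14 to 0.22. Limma called 0 genes, with 1268 at an unadjusted p under 0.05, as values shrank and errors rose with a covariate that follows the genotype. A lower share of fat cells would lower all mature adipocyte genes alike if only fat cells made this RNA and signals were linear. Of that list, 33.3% (9 genes) lay over 2 of their own SE from its median, so its genes did not fall alike. Neither condition was tested, so dilution is not excluded. Sex was not balanced either, as control replicate 2 had the pattern of a female embryo and the other arrays that of males. Its part was not tested. Loss of MED1 in the precursors remains an untested hypothesis, which staining of muscle and fat in the same dissections would test.

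The macrophage list was higher by camera in adult Adipoq-Cre knockouts, with no gene of 21 called and an adjusted p = 0.33 with an estimated correlation, and its effect differed from that in embryos by 1.01 (list median). Fewer fat cells, which raises every other cell type alike, might be the whole cause. The macrophage median of 1.28 (SE 0.11) lay at least 5.0 SE above those of endothelial (-0.14), Schwann (-0.03) and smooth muscle genes (-0.1). Here the SE of a list median measures the spread between its genes, not between the 4 arrays. The distance in SE is thus no test across animals, though the medians of these lists did not rise alike. Fibroblast matrix (0.63, SE 0.07) and lymphocyte genes (0.24, SE 0.13) were higher too, so a lower share of fat cells stays open, at least as a part. Without any 1 of the 4 arrays the median was 1.03 to 1.45, so no single array carried it. More macrophages, or more RNA of these genes per macrophage, are open, and so are age, Cre line and control genotype, which differ together between the sets; counts of macrophages in sections would test the first.

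The interferon list was lower by camera in knockout than in wild-type cells on day 0 by the title, with 5 of 26 genes called and an adjusted p = 0.105 with an estimated correlation, and the genotype difference changed by 0.77 between the days (list median), or by -0.28 with the source label for the day. Without any 1 of the 8 arrays the day 0 median was -1.1 to -0.83, so no single array carried it. Only leaving out a day 0 array can change this median, which then rests on 1 array against 2. Dishes might differ in interferon response whatever their genotype. With 2 arrays per genotype, which the labels do not place in separate dishes, this cannot be told apart from an effect of MED1. The exact permutation p of 0.333 is what any 2 against 2 arrays without overlap give and decides nothing. Wrong titles would undo the day 0 groups, but 4 of 4 arrays with conflicting labels were closer to the array on their title day. Differences between the pooled clones and the parent line other than loss of MED1 stay open too. Repeats from independently made clones and thawed dishes would test the remaining explanations.

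Other differences between the knockout effects on day 2 and day 0, each a list median past camera, were -0.24 (cell cycle), -0.3 (mature adipocyte), -0.16 (citric acid cycle) and -0.1 (white fat). With an estimated correlation their adjusted p was 0.84, 0.151, 0.278 and 0.258. Without wild-type day 0 replicate 1 the cell cycle median was -0.01 with the camera direction turned, and with the source label those of mature adipocyte and white fat were 0.02 and 0.06. Between adult and embryonic brown fat 441 genes differed by a test of the difference, in a fit with 1 estimate of the spread for both sets. Among the named genes the differences were 3.22 (Cpt1a), 3.14 (Ptges), 3.1 (Nr4a2), 2.88 (Aqp11), -4.28 (Cyp2e1), -2.56 (Rhou), -2.35 (Ppargc1b) and -2.35 (Retn). Those of list members were -0.79 (Ube2c), 0.62 (Psmb8), 1.41 (Cd3e), 0.83 (Cd4), 0.69 (Nkg7), 1.52 (C1qc), 1.63 (H2-Aa), 1.47 (Cd14), 0.82 (Ccng1) and 0.91 (Suclg2). List medians differed by -0.26 (adipogenic regulators), -0.6 (cell cycle), 0.5 (cholesterol synthesis), 0.34 (fatty acid oxidation), 0.39 (interferon) and 0.24 (lymphocyte). The others were 0.2 (nuclear respiratory chain), 0.35 (p53 targets), -0.92 (skeletal muscle), 0.26 (citric acid cycle) and 0.35 (unfolded protein response). None of these lists passed with an estimated correlation.

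In Myf5-Cre knockout embryos, single arrays stood apart from the other 3 by Dixon's ratio: replicate 4 for Cidea (0.84), replicate 1 for the means of the sex-linked (0.87) and skeletal muscle lists (0.96), and replicate 3 for the white fat list (0.86). These are above the ratio that 1 in 20 groups of 4 passes by chance. Of 51 values tested 4 were above it, where chance gives 2.5. Transcript clusters without a gene symbol are outside the comparisons of genes: of 16010, limma called 3 between knockout and wild-type cells, 13 between days in wild-type cells, 6 between days in knockout cells, 1 in adult brown fat and 4 between the adult and embryonic effects.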

How the results depend on the processing

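All alternatives of this part were chosen before the data were examined. With the source label for the day of the cell arrays, limma called 1 gene on day 0, 0 on day 2 and 0 between days in either genotype, with 434, 490, 650 and 559 at an unadjusted p under 0.05 (1109 by chance). Embryonic calls ended without any 1 of the 7 arrays (0 called by limma, 2991 to 4548 unadjusted) and with the muscle covariate (0, with 1268 unadjusted), and adult calls without any 1 of 4 (0, with 1984 to 2333). For the genotype over all cells, 245 genes were called with trend and robust fitting, 198 without the dimmer genes, 177 with all 19 arrays, 20 to 32 without 1 array and its pair, and 30 with a 2-fold limit. Without the pair block limma called 79 genes with days by the title, 38 of them among the 64 with the block, and 9 with days by the source label. On day 0 the counts were 88 with all 19 arrays, 74 unadjusted with 2-fold and 3 to 40 without 1 array; on day 2, 120 with all 19 arrays and 12 to 47 without 1. Between days a 2-fold limit gave 674 (699 unadjusted) in wild-type and 499 (526 unadjusted) in knockout cells, and leaving out 1 array 1143 to 1714 and 496 to 1282. The difference between days gave 11 with all 19 arrays, 88 unadjusted with 2-fold and 0 to 2 without 1 array. In the embryo the counts were 1296 without the dimmer genes, 386 with centring, 146 with array weights, 1527 with all 19 arrays, and 47 with a 2-fold limit (159 unadjusted). In the adult they were 78 with trend and robust fitting, 107 without the dimmer genes, 64 with quantile normalization, 64 with centring, 2049 with all 19 arrays and 545 unadjusted with 2-fold. For adult against embryo they were 128 with array weights, 773 with all 19 arrays, 232 with a 2-fold limit and 206 to 524 without 1 array.

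The labels do not say that a replicate number marks a shared culture, animal or day, so no main block was chosen by it. The pairs of the genotype comparison over all cell arrays came from the day labels. The arrays of each pair also share their replicate number, so that comparison is in effect paired by it within a title day. Deviations of arrays with the same number correlated by 0.35 (day 0) and 0.3 (day 2) between genotypes, 0.03 and 0.17 between days, 0.31, -0.02 and 0.11 in the embryo and 0.33 in the adult; groups of 2 arrays give 1 such value each, a hint of shared conditions at most. A block by replicate number gave 54 genes on day 0, 86 on day 2, 2555 and 1660 between days, 338 for adult against embryo, 139 in the adult, 1 for the difference between days and 0 by limma in the embryo (3844 unadjusted).

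An uncalled gene counts as turning its sign only where its size exceeds its standard error. Groups by the source label hold 1 array of each title day, so they mix the days if the titles are right. By correlation, 4 of 4 arrays with conflicting labels went with their titles. With the source label for the day, these log2 values turned sign. On day 0: Plin1 -0.36, Prdm16 -0.06. Between days in wild-type cells: Pparg -0.16, Cebpa -0.03, Fabp4 -0.27, Plin1 -0.39, Lpl -0.53, Srebf1 -0.37, Mlxipl -0.02, Ucp1 -0.06, Ppargc1a 0.15, Prdm16 -0.21, Pip -0.58, Orm3 -0.4, Cxcl13 -0.12, Oasl2 0.69, Usp18 0.79, Ifit1 0.86, Mx2 0.42, Apol9b 0.39, Rtp4 0.33, Klf5 -0.03, Zbtb16 -0.23, Ccne1 -0.04, Cnn2 0.03, Thbs2 0.2, Col1a2 0.02, Fkbp5 -0.1, Egln3 -0.11, Vegfa -0.32, Irf9 0.19, Retn -0.17, Cyc1 -0.06, Pcx -0.33, adipogenic regulators list -0.16, hormone cocktail response list -0.03, interferon response list 0.23, mature adipocyte list -0.03. Between days in knockout cells: Cebpa -0.17, Srebf1 -0.54, Mlxipl -0.03, Ppargc1a 0.41, Orm3 -0.52, C1s2 0.07, Oasl2 0.18, Usp18 0.05, Cebpd -0.11, Dcn 0.19, Thbs2 0.25, Vegfa -0.33, Egln3 -0.05, Ifit2 0.12, Mx2 0.04, Rps7 -0.17, Rps14 -0.3, adipogenic regulators list -0.1, hypoxia glycolysis list -0.05, interferon response list 0. For the genotype by day difference: Pparg 0.21, Fabp4 0.69, Adipoq 0.02, Plin1 0.22, Lpl 0.1, Ucp1 0.09, Prdm16 0.17, Pcna 0.01, Oas2 -0.4, Rtp4 -0.34, Mx2 -0.38, Retn 0.3, Pcx 0.16, Idh3a 0.03, Agt 0.58, interferon response list -0.28, mature adipocyte list 0.02, white adipocyte list 0.06. Leaving out 1 array turned signs on day 0: Cd36 ran from -0.06 (without knockout day 0 replicate 1) to 0.51, and the cholesterol synthesis list was at 0.1 without that array. Without wild-type day 0 replicate 2, Acly was at 0.1, Ppargc1a at 0.01, Mvk at 0.02, the cell cycle list at 0.02 and the cholesterol synthesis list at 0.19; without wild-type day 0 replicate 1, Acly was at -0.55, Mvk at -0.63 and these lists at -0.48 and -0.65. Cebpb on day 2 ran from -0.35 to 0.03 (without wild-type day 2 replicate 2), and Lpl in the adult from -0.76 to 0.06 (without control replicate 2). For lists the camera direction counts: without wild-type day 0 replicate 1 it turned for the cell cycle list of the genotype by day difference, with a median of -0.01. The muscle covariate turned Med1 (0.25) and Elovl3 (0.7) in the embryo. With the arrays whose day labels agree, where no test was run, 53 values of called genes moved by over 1 SE and 59 did not.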

Other observations

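The comparisons of the brown fat models with each other and with the cell line were chosen after the results were seen; the count of splits in cells and the test of the day labels were chosen before the data were examined, but the limit to splits that part all pairs was set after. Perm1, Coq8a, Nrg4, Alpl, Ccnd2, Vcam1, Igfbp4, Xist and Eif2s3y are outside the naming rule, and others are named here in a set where the rule did not pick them.

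By a looser rule, an unadjusted p under 0.005 and a log2 fold change of at least 0.9 in the same direction in both brown fat sets, 27 genes were found, and 24 of them were lower. Lncbate10 passed over all genes in both (log2 fold change -2.12 in the embryo and -4.11 in the adult). Ppara, a receptor that drives fatty acid burning, had values of -1.29 and -3.46, Pdk4 of -1.31 and -1.72, Cidea of -1.21 and -1.37, Pank1 of -1.76 and -2.18, Perm1 of -1.46 and -2.68, Coq8a of -1.1 and -2, and Nrg4, a hormone of brown fat, of -0.98 and -0.92. Scd1 (-2.62 and -1.09), Slc25a20 (-1.43 and -0.99) and Pck1 (-1.56 and -3.24) were on the same side. Alpl (0.96 and 1.92), Ccnd2 (1.03 and 1.54) and Vcam1 (1.16 and 1.72) were higher. In the adult, the adjusted p was 0.049 for Lncbate10 and 0.052 to 0.14 for the other 26 of the 27 genes. In the embryo 12 passed, and the other 15, with Ppara, Pdk4, Cidea, Perm1, Coq8a, Nrg4, Pck1 and Vcam1 among them, passed in neither set (adjusted p = 0.053 to 0.086 in the embryo).

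Of 146 genes called higher in the embryo, 105 were higher in the adult knockout too, and of 111 called lower, 95 were lower. At an unadjusted p under 0.05 in both, 977 genes had the same sign and 145 opposite signs, where chance gives 302 each if genes vary independently. Genes that vary together can give an excess of either kind without an effect of genotype. These counts therefore decide nothing, and the splits of the arrays are the test. The correlation of fold changes was 0.33, and 6 of 210 pairings of splits of the arrays gave one as high, with 0.35 the highest of the others. The 2 models may thus share changes, a hypothesis that a Cre line active in both ages would test; the 6 pairings count the real one.

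Genes called in the cell line did not go with the embryonic changes. Of 64, 27 had the same sign in embryonic brown fat, and 29 of 35 splits gave as many (42 in the highest other). In adult brown fat 29 of 64 had the same sign. Pdk4 was lower in cells (-1.33), embryo (-1.31) and adult (-1.72), while Mest, at -3.89 in cells, had values of 0.1 and 0.44, and Igfbp4, at -1.2 in cells, of 0.71 and 0.72. The real split of the cell arrays called 64 genes and the highest other of the 8 splits that part all 4 pairs called 0, and 8 splits are too few for a share under 0.05. The planned count took in 24 more splits, with 26 genes in the highest, but these part only 2 of the pairs and so rest on 4 arrays.

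The arrays whose day labels conflict went with their titles: 4 of 4 correlated more with the array that both labels put on the title day. In wild-type cells the values were 0.9895 against 0.9766 and 0.9915 against 0.9744, and in knockout cells 0.9926 against 0.9819 and 0.9934 against 0.9835. The mean of the hormone response list, read after the results were seen, went the same way. It was 6.97 to 7.08 in the arrays titled day 0 and 8.42 to 8.62 in those titled day 2, whatever their source label. These values argue against the source label as the day of the arrays with conflicting labels. In embryonic brown fat, Xist was 9.07 and Eif2s3y 2.97 in embryonic control replicate 2, and 2.37 to 2.58 and 6.82 to 7.82 in the other 6 embryonic arrays, the pattern of a female embryo among males. Sex was thus not balanced between the embryonic genotypes. Lep in adult brown fat was 8.1 and 5.68 in controls and 7.73 and 4.17 in knockouts, and in each genotype replicate 1 had less Dio2 and more Lep than replicate 2. Endothelial, Mediator subunit, cartilage and bone, Schwann, erythroid and sex-linked lists passed camera in no comparison, with smallest adjusted p of 0.183, 0.193, 0.281, 0.323, 0.328 and 0.546.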
